A study of Homo sapiens with 16 samples.

How the data were processed

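The series holds poly-A RNA sequencing of primary human skeletal muscle cells in culture. Per the labels, cells were transfected with siRNA against VDR, the nuclear receptor for vitamin D, or with scrambled siRNA. From 48 h after transfection they received 1,25(OH)2D3 (calcitriol, the active hormone form of vitamin D) at 10 nM in ethanol, or ethanol alone, added 48 h and again 24 h before RNA was isolated. There were 4 groups of 4 libraries, 16 in all, sequenced as paired reads of 51 bases. The labels do not say whether the replicates of a group are separate cultures, dishes or donors, so p-values measure only the spread between these samples.

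The deposited table gave, for 23398 gene rows, counts and RPKM for each library, per the file headers. Mapping and counting are credited, per the submitters' processing notes, to CASAVA, TopHat2, HTSeq and edgeR with hg19, without versions, roles or strand setting. All 374368 deposited counts were even, so each fragment appears as a step of 2, and the fragment numbers given here are the deposited counts divided by 2. For each library the total implied by counts, gene lengths and deposited RPKM was taken as a median over genes with high counts. The listed counts made up 68.5 to 77.4% of that total. Whether single genes gave the same total is not reported here. The counts were analysed and the RPKM were used only for that total. Left out were 21 copies of pseudoautosomal genes with counts identical to those of the X copy, and 104 further entries on the Y chromosome or for transcripts of X inactivation, so that no donor's sex is read from the data. This left 23273 entries. No mitochondrially encoded gene was in the table, so the list of 13 mitochondrially encoded mRNAs could not be tested.

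Library totals ran from 200384064 to 351455266 deposited counts, and 17969 to 19121 genes were detected. Genes at a count of 0 over a group were given a floor of 3 fragments over the group. Intervals are 95% and, like the floors, cover counting error only. With no strand setting stated, reads of genes that overlap on the genome cannot be assigned with certainty. Among the named genes this applies to SULT1C2, FER1L6, EMILIN3, CYP3A7, HMCN1, COL8A1, RXRA and CHRM2.

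The tests were fixed before the data were examined. Counts were scaled by TMM, filtered with filterByExpr to 18559 genes, and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, robust=FALSE, 1 mean per group, all 16 libraries). The 5 contrasts were the calcitriol effect in scrambled siRNA cells and in VDR siRNA cells, the VDR siRNA effect in ethanol and with calcitriol, and the interaction. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p-values of genes in the report are from this edgeR quasi-likelihood test. CPM are TMM-scaled, and ± gives the SD over 4 libraries. Library measures and VDR were compared with exact two-sided permutation tests, whose smallest p for 4 against 4 is 0.0286.

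Genes were named by a rule fixed in advance. In each pairwise comparison it took up to 10 rises and 10 falls with the largest log2 fold change among genes past the threshold, with a mean of at least 1 CPM and all 4 libraries of 1 group above all 4 of the other. For the interaction it took the 10 smallest p, and 14 genes of vitamin D action, mitochondrial dynamics and myogenesis were given whatever their p. Of each list described, up to 4 called members with the smallest p could be named. The lists, also fixed in advance from general knowledge, covered vitamin D receptor target genes, vitamin D metabolism and receptor partners, nuclear OXPHOS subunits, mitochondrial dynamics and biogenesis, pyruvate dehydrogenase and citric acid cycle, glycolysis, fatty acid oxidation and lipid storage, myogenic regulators and myoblast markers, sarcomere and contractile genes, muscle atrophy and protein turnover, and calcium handling. They also covered cell cycle, cell cycle inhibitors and p53 targets, extracellular matrix, TGF-beta response, inflammatory and NF-kB genes, type I interferon response, cholesterol synthesis, hypoxia and angiogenesis, unfolded protein response and amino acid stress, oxidative stress response, cytosolic ribosomal proteins, immediate early genes, and markers of fibroblasts, pericytes and smooth muscle, endothelium, leukocytes and adipocytes. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list with all other genes, with adjustment over 140 tests. The camera test was repeated with a correlation estimated for each list, and fry was run beside it.

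Alternatives were other size factors, DESeq2 1.42.0, limma-voom, other filters on low counts, robust=TRUE, only the compared libraries in the fit, replicate number as a block, and each library left out in turn. Halved counts, leaving out 2 libraries that carried unusual transcripts, the target lists without CYP24A1, and removal of a trend with GC content and gene length were chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the 3′ UTR word counts and figures.

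The steps were tested on simulated data. With 200 of 18287 genes changed, edgeR called 38% of 50 genes changed by 0.25 on the log2 scale, 56% at 0.5, 68% at 1 and 74% at 2, and 2 of the 120 calls were false. A list of 40 genes moved by 0.3 was called by camera and none of the other lists was. The simulated genes were drawn independently, so this does not test camera on lists of correlated genes. In the real data the estimated correlation reached 0.729, in ribosomal proteins for calcitriol in scrambled siRNA cells. A 3′ UTR word planted with an effect of -0.2 came back at -0.196 on average and ranked lowest in 20 of 20 runs.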

Results

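VDR siRNA lowered the transcript of its target, the vitamin D receptor, in both media. VDR stood at 8.46 ± 0.621 CPM in scrambled siRNA cells and 2.14 ± 0.168 CPM in VDR siRNA cells in ethanol, leaving 25.3% (log2 fold change -1.98, SE 0.095, edgeR quasi-likelihood adjusted p = 2.78e-13). With calcitriol it stood at 7.86 ± 0.724 and 2.54 ± 0.227 CPM, leaving 32.3% (-1.63, SE 0.095, adjusted p = 5.04e-12). The groups did not overlap in either medium (exact permutation p = 0.0286, n = 4 per group, the smallest p this design allows). Calcitriol itself left no called change in VDR in scrambled siRNA cells (log2 -0.11, adjusted p = 0.578).

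Calcitriol raised part of the vitamin D receptor targets in scrambled siRNA cells, CYP24A1 most clearly, and other genes besides. CYP24A1, the hydroxylase that inactivates calcitriol, went from 6 fragments over the 4 ethanol libraries, all in replicate 3, to 145393 fragments over the 4 calcitriol libraries. This is a ratio of 26400-fold with a 95% counting interval of 12100 to 71900, and with replicate 3 left out the ethanol libraries held none. Among the other rises named by the rule were PVALB, which encodes the calcium buffer parvalbumin (4.44 on the log2 scale, SE 0.366, from 0.0885 to 1.95 CPM), and the adaptor gene SHE (3.96, SE 0.208). DPP4, a cell-surface peptidase that cleaves incretins, went from 7.20 ± 0.945 to 38.8 ± 3.85 CPM (2.43, SE 0.094, edgeR adjusted p = 1.37e-13). The sulfotransferase gene SULT1C2 rose by 3.27, the myeloid receptor gene TREM1 by 2.83, FAIM2, an inhibitor of Fas-driven cell death, by 2.72, the potassium channel subunit gene KCNS2 by 2.71, the ferlin family gene FER1L6 by 2.14 and the transcription factor gene OSR2 by 2.05.

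The falls named by the rule were smaller than the rises. The natriuretic peptide convertase gene CORIN went from 18.7 to 7.91 CPM (-1.24, SE 0.086). SCG2, a secretory granule protein gene, changed by -1.46, EMILIN3 of the matrix by -1.28, the oestrogen sulfotransferase gene SULT1E1 by -1.21 and CNN1, encoding the smooth muscle protein calponin, also by -1.21. The remaining falls were GUCY1A2, a subunit of the nitric oxide receptor (-1.17), the lipid droplet gene CIDEC (-1.08), FMO2 and MMP28 (both -1.03), and MYH2, a fast myosin heavy chain (-1.02). PDK4, the kinase that shuts pyruvate dehydrogenase, fell by 0.86 on the log2 scale (7.17 to 3.94 CPM), and myostatin (MSTN), the inhibitor of muscle growth, fell by 0.50. VEGFA, the angiogenic factor, rose by 0.47, and RXRA, the receptor's dimer partner, changed by -0.18 (edgeR adjusted p = 0.017). MYOG, the driver of myoblast fusion, had a log2 fold change of -0.42 (edgeR adjusted p = 0.0395) that was lost without scrambled ethanol replicate 1 or 2 or scrambled calcitriol replicate 2 or 3 (adjusted p up to 0.118), and MYOD1 was not called (-0.44, adjusted p = 0.109).

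In all, 1630 of 18559 genes were called, 658 higher and 972 lower, and 94 rose and 33 fell at least 2-fold. The 658 became 432 without scrambled ethanol replicate 3, and 1149 (of 2851 called) with only the compared libraries in the fit and 1066 (of 2432) after a trend with GC content and gene length was removed. Of the 94, 13 were among 49 transcripts raised in scrambled calcitriol replicate 1 alone or there and in 1 other library, described last. Without the 2 libraries concerned 1350 genes were called. The scrambled calcitriol libraries also read GC-rich transcripts slightly lower than the ethanol ones, with a gap between GC-rich and GC-poor genes of -0.128 ± 0.069 against 0.017 ± 0.042 on the log2 scale (exact permutation p = 0.0286, n = 4, adjusted p = 0.114 over 4 comparisons).

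Of 51 tested vitamin D receptor targets, 19 rose and 1 fell (21 and 3 adjusted over the list alone). Besides CYP24A1 and SHE, the examples were CLMN, a calponin-domain membrane protein gene (1.66), and EFTUD1, a ribosome assembly GTPase gene (1.88). Their list moved up against all other genes (camera adjusted p = 3.78e-46, and adjusted p = 1.12e-07 with an estimated correlation). Cholesterol synthesis fell, with 15 of 31 genes lower and none higher (20 adjusted over the list alone), among them the fatty acid desaturase gene FADS2 (-0.36). That call held with an estimated correlation (adjusted p = 0.0148). The list of vitamin D metabolism and receptor partners was also called, through CYP24A1 alone, and without that gene it had an adjusted p of 0.989.

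Muscle and matrix lists moved down by camera under the preset correlation only. The fry adjusted p was 0.0621 for the sarcomere, 0.00184 for pericyte and smooth muscle markers and 0.0175 for the matrix. For the further lists below it was 0.205 for interferon, 0.0208 for p53 targets, 0.00501 for inflammatory and 0.234 for cell cycle genes. Of 46 sarcomere genes 11 fell (15 adjusted over the list alone), including the nebulin relative NEBL (-0.70) and tropomyosin TPM1 (-0.29), and with an estimated correlation the adjusted p was 0.596. Of 17 pericyte and smooth muscle markers 6 fell and 1 rose (10 and 2 adjusted over the list alone, adjusted p = 0.179 with an estimated correlation). TAGLN, a smooth muscle actin-binding protein gene, fell by 0.70 and ALPL, tissue alkaline phosphatase, rose by 0.65. Of 52 matrix genes 23 fell and 12 rose (25 and 13 adjusted over the list alone, adjusted p = 0.596 with an estimated correlation), with COL8A1 at -0.78, thrombospondin THBS1 at -0.45, the collagenase MMP1 at 1.72 and laminin LAMA4 at 0.51. Of 38 interferon genes 6 fell (9 adjusted over the list alone, adjusted p = 0.781 with an estimated correlation), and of 30 p53 targets and cell cycle inhibitors 3 fell (5 adjusted over the list alone, adjusted p = 0.554). Inflammatory genes moved up, with 7 of 35 higher and 2 lower (10 and 3 adjusted over the list alone, adjusted p = 0.334 with an estimated correlation), among them the chemokine CXCL12 (0.63) and the IL-33 receptor IL1RL1 (1.64). Of 47 cell cycle genes 3 rose, also over the list alone. That list's adjusted p of 0.0295 became 0.782 with an estimated correlation, 0.377 without scrambled ethanol replicate 1, 0.106 without scrambled calcitriol replicate 1 and 0.129 without scrambled calcitriol replicate 3.

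In VDR siRNA cells calcitriol still induced CYP24A1, but few other genes passed the test. CYP24A1 went from no fragment in the 4 ethanol libraries to 12584 fragments, at least 4880-fold against a floor of 3 fragments over the group. KCNS2 rose by 0.93 on the log2 scale (edgeR adjusted p = 0.00138) and OSR2 by 0.74 (adjusted p = 0.00535). The other called genes, all higher, were FER1L6 (1.44), SHE (1.10), CHRDL1, a BMP antagonist gene (0.55), EFTUD1 (0.45), CLMN (0.41), SULF1, a heparan sulfate sulfatase gene (0.32), and ELFN2 (0.32). These 10 were all the genes called, against 1096 at an unadjusted p under 0.05. With the replicate number as a block 7 genes were called, 6 of them among the 10, and with limma-voom 8, of which 7 were. CYP24A1, KCNS2 and OSR2 stayed past the threshold with each of the 8 libraries left out alone, whereas each of the 8 ended at least 1 of the other 7 calls, so the count was 3 without VDR siRNA ethanol replicate 3 or calcitriol replicate 2, 5 without ethanol replicate 2, 6 without ethanol replicate 1 and 15 without calcitriol replicate 1. With only the compared libraries in the fit 2 genes were called, CYP24A1 and KCNS2, and OSR2 was not (0.75, adjusted p = 0.159). The VDR siRNA libraries differed among themselves in how they read GC-rich genes, from -0.323 in calcitriol replicate 3 to 0.38 in calcitriol replicate 1, and with that trend removed 24 genes were called.

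Vitamin D receptor targets again moved up in VDR siRNA cells, with 4 of 51 called (5 adjusted over the list alone, adjusted p = 6.23e-06 with an estimated correlation). Vitamin D metabolism and receptor partners moved up through CYP24A1 alone (adjusted p = 0.431 without it). A further 6 lists were called downward with 0 members called (1 sarcomere gene adjusted over the list alone), and with an estimated correlation their adjusted p was 0.596 for OXPHOS subunits, 0.891 for ribosomal proteins, 0.781 for cell cycle, 0.768 for oxidative stress, 0.596 for pyruvate dehydrogenase and citric acid cycle, and 0.909 for the sarcomere. Of these, OXPHOS was called whichever library was left out. VDR siRNA calcitriol replicate 2, left out, ended the calls of the other 5 (adjusted p 0.917 for ribosomal proteins, 0.0906 for cell cycle, 0.385 for oxidative stress, and 0.187 for each of the last 2). Calls also ended without VDR siRNA ethanol replicate 1 (ribosomal 0.086, oxidative stress 0.0507, sarcomere 0.763), 2 (cell cycle 0.335), 3 (oxidative stress 0.0581, citric acid cycle 0.0867) or 4 (citric acid cycle 0.213), and without VDR siRNA calcitriol replicate 1 (cell cycle 0.116, citric acid cycle 0.0928) or 3 (ribosomal 0.533, sarcomere 0.794). Among the other libraries, which enter only through the shared scaling, filter and dispersion, scrambled calcitriol replicate 3 (citric acid cycle 0.052) and scrambled ethanol replicate 1 (sarcomere 0.0567) did the same.

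**Figure D1:**
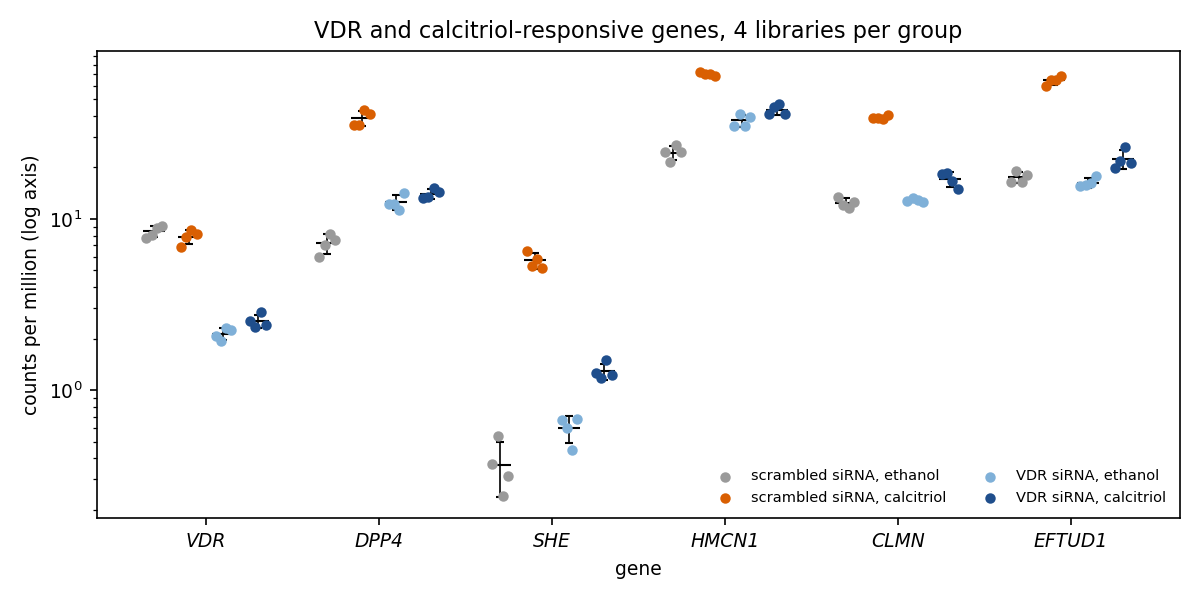
Level in CPM (log axis) of VDR and of 5 genes with a called interaction (DPP4, SHE, HMCN1, CLMN, EFTUD1) in the 4 groups, with points for libraries, a dash for the mean and a bar for the SD. In scrambled siRNA cells DPP4 went from 7.20 CPM in ethanol to 38.8 CPM with calcitriol.

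The calcitriol response was smaller with VDR siRNA. The interaction was called for 331 genes, and 326 of them were also called for calcitriol in scrambled siRNA cells, a selection that nearly fixes a smaller effect in VDR siRNA cells. It was called for 504 genes with DESeq2 and 748 after removal of the GC and length trend. DPP4 rose by 2.43 in scrambled siRNA cells and had 0.17 in VDR siRNA cells (interaction -2.26, SE 0.128, edgeR adjusted p = 8.27e-10). Its ethanol level was also higher with VDR siRNA, at 11.2 to 14.3 CPM against 5.98 to 8.22 CPM in scrambled siRNA cells. The matrix gene HMCN1 (-1.32), CLMN (-1.25), EFTUD1 (-1.43), the neuronal pentraxin gene NPTX2 (-0.88), the protease inhibitor SERPINE2 (-0.62), TREM1 (-2.54), the osteoblast membrane protein gene TMEM119 (-0.88) and SHE (-2.86) had a lower value with VDR siRNA, and COL8A1, which calcitriol lowered, a higher one (0.64). CYP24A1 had an interaction adjusted p of 0.916, since its ethanol groups lie at the floor, yet its level with calcitriol was 25.2 ± 2.51 CPM in VDR siRNA cells against 271.5 ± 31.1 CPM in scrambled siRNA cells. Over the 1630 genes, 1262 (77.4%) kept their sign in VDR siRNA cells and 10 were called there in the same direction, where 0.4 would be met by chance. The median change in the direction of the scrambled siRNA cells was 0.293 and 0.056 on the log2 scale. As the genes and their directions were chosen in scrambled siRNA cells, the selection by itself favours the larger value there. Across these genes, which are not independent replicates, Pearson's r was 0.34 and Spearman's rho 0.534.

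**Figure D2:**
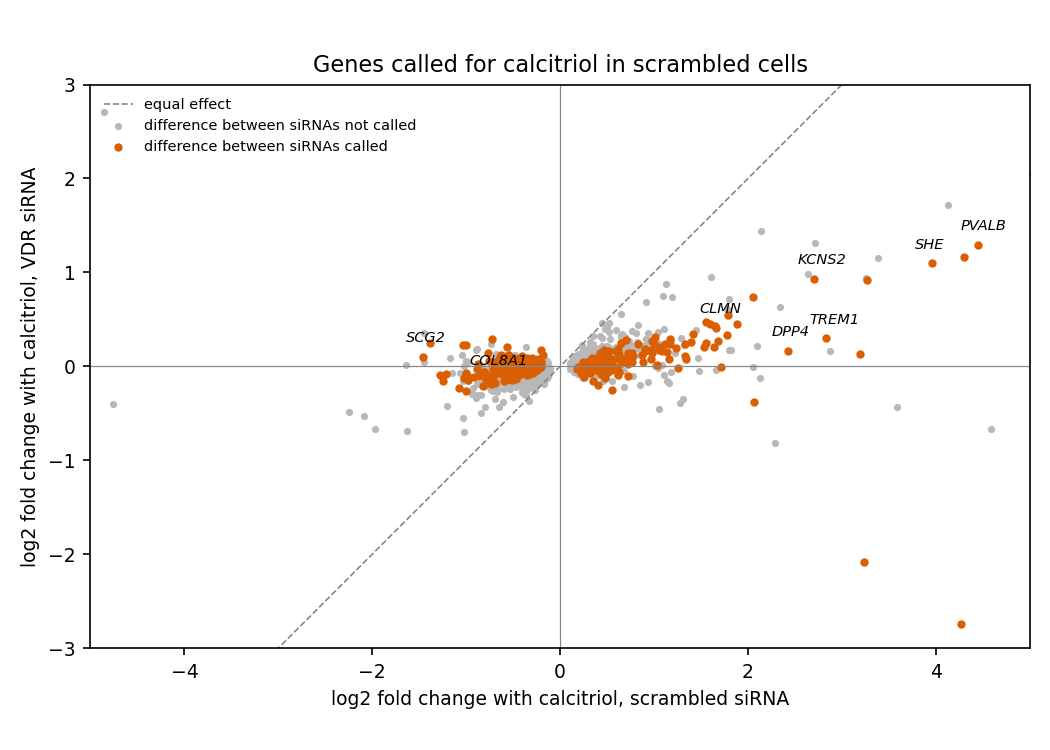
Calcitriol effect (log2 fold change) in scrambled siRNA cells (horizontal) and VDR siRNA cells (vertical) for 1629 genes called in scrambled siRNA cells, with CYP24A1 left out and 10 genes outside the axes. Orange points mark the 326 genes with a called interaction.

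Among lists, vitamin D receptor targets had 10 members with a smaller response (18 adjusted over the list alone, adjusted p = 6.23e-06 with an estimated correlation), and 3 cholesterol synthesis genes had a smaller fall (6 adjusted over the list alone, adjusted p = 0.0214). The remaining called lists lost the call with an estimated correlation. Their adjusted p was then 0.726 for the sarcomere (1 higher, NEBL), 0.768 for interferon genes (1 higher), 0.596 for cell cycle (1 lower), 0.209 for pericyte and smooth muscle markers (2 higher, and 6 higher and 1 lower adjusted over the list alone) and 0.254 for inflammatory genes (2 lower, 3 adjusted over the list alone). It was 0.768 for the matrix list (9 higher and 5 lower, and 17 and 10 adjusted over the list alone), which was called upward while its median was 0.07 and mean -0.02. The matrix call was also lost without VDR siRNA calcitriol replicate 1 (adjusted p = 0.0954) or replicate 4 (adjusted p = 0.0527).

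VDR siRNA changed more genes than calcitriol did, and glycolysis, cholesterol synthesis and cell cycle were among the lists that fell. In ethanol, PDK4 went from 7.17 ± 0.759 to 59.6 ± 7.04 CPM (log2 fold change 3.06, SE 0.096, edgeR adjusted p = 3.16e-16). SCD, the desaturase that makes monounsaturated fatty acids, went from 1104 to 243 CPM (-2.18, SE 0.046, adjusted p = 1.56e-18). The guidance cue NTN1 rose by 3.72, the arginine deiminase gene PADI2 by 3.36, the muscle sodium channel gene SCN4A by 3.30, CLCA2 by 3.29, the phosphoinositide phosphatase gene INPP5D by 3.09, C1orf187 by 3.03, the cytochrome P450 gene CYP3A7 by 2.97 and PVALB by 2.96. The carboxypeptidase gene CPA4 went from 66.2 to 6.64 CPM (-3.32), and ISM2 (-3.09), the glycosyltransferase gene MGAT3 (-2.99), the peptide hormone apelin APLN (-2.50), C2orf72 (-2.40), the adhesion gene L1CAM (-2.32), the muscarinic receptor gene CHRM2 (-2.21) and the semaphorin gene SEMA7A (-1.88) fell. KIT also passed the rule (3.67, adjusted p = 0.0423), but through VDR siRNA ethanol replicate 2, without which it stood at 1.45 (adjusted p = 0.452), and leaving out any 1 scrambled ethanol library ended that call too (adjusted p 0.0849 to 0.0999).

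Of 18559 genes, 7527 were called in ethanol, 3830 higher and 3697 lower, with 480 and 354 of them changed at least 2-fold, and 9 of the 480 were among the unusual transcripts of VDR siRNA ethanol replicate 2. PPARGC1A, the coactivator of mitochondrial biogenesis, rose from 1.23 to 2.82 CPM (log2 fold change 1.2, SE 0.218 on that scale). MSTN rose by 1.14, while VEGFA fell by 1.04 and RXRA by 0.22. The fusion gene MFN2 rose by 0.26. DNM1L, the fission GTPase, had -0.14 (edgeR adjusted p = 0.0367) and lost the call without scrambled ethanol replicate 3 or 4 or VDR siRNA ethanol replicate 1 or 2 (adjusted p up to 0.135). Not called were OPA1 (-0.03), FIS1 (0.14), MFN1 (-0.06), MYOD1 (0.23) and MYOG (-0.31, adjusted p = 0.0529), although MYOG passed without scrambled ethanol replicate 3 (0.0473) or 4 (0.0228) or VDR siRNA ethanol replicate 1 (0.024). In the calcitriol comparison of scrambled siRNA cells none of these 6 mitochondrial genes was called by edgeR, at 0.06 for OPA1 (0.055), -0.08 for FIS1, -0.07 for DNM1L, 0.02 for MFN1, -0.09 for MFN2 and 0.05 for PPARGC1A.

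Cell cycle genes fell as a group, with 43 of 47 lower and 2 higher (the same adjusted over the list alone), among them the spindle gene DLGAP5 (-1.31), ribonucleotide reductase RRM2 (-1.17) and UBE2C (-1.04). Of 30 cell cycle inhibitors and p53 targets 21 rose and 3 fell (23 and 3 adjusted over the list alone), including TP53I3 (1.62), TP53INP1 (1.65), the stress gene SESN1 (1.46) and the antiproliferative gene BTG2 (1.46). Glycolysis fell in 22 of 26 genes with 1 higher (23 and 1 adjusted over the list alone), as in the enolases ENO2 (-1.47) and ENO1 (-1.04) and phosphoglycerate kinase PGK1 (-0.93). Cholesterol and fatty acid synthesis fell in 26 of 31 genes with 2 higher (the same adjusted over the list alone), with the sterol sensor INSIG1 at -1.08 and ACAT2 at -0.94. Hypoxia genes fell in 19 of 33 with 8 higher (the same adjusted over the list alone), with adrenomedullin ADM at -1.13 and carbonic anhydrase CA9 at -1.54. These calls held with an estimated correlation, at camera adjusted p of 0.0294, 0.000713, 0.0107, 0.00212 and 0.0362 in that order.

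Another 5 lists were called in ethanol by camera under the preset correlation only. Their fry adjusted p was 0.00298 for interferon genes, 2.57e-06 for the matrix and 2.19e-07 for the unfolded protein response. It was 2.01e-06 for muscle atrophy and 0.0774 for the sarcomere. Interferon genes rose in 28 of 38 with none lower (31 adjusted over the list alone, adjusted p = 0.768 with an estimated correlation), such as the antiviral GTPase MX1 (2.04), STAT2 (0.65) and OASL (1.44). Matrix genes fell in 28 of 52 and rose in 15 (29 and 16 adjusted over the list alone, adjusted p = 0.377 with an estimated correlation), with the protease inhibitor TIMP3 at -1.68 and the collagen chaperone SERPINH1 at -1.43. Stress genes of the unfolded protein response list fell in 16 of 31 and rose in 2 (17 and 3 adjusted over the list alone, adjusted p = 0.209 with an estimated correlation). Their examples were the amino acid transporter SLC7A5 (-1.75) and CHAC1 (-1.35), against the disulfide isomerase PDIA4 (1.11). Muscle atrophy genes rose in 13 of 29 and fell in 6 (the same adjusted over the list alone, adjusted p = 0.314 with an estimated correlation), with the ubiquitin ligase FBXO32 at 1.80, FOXO1, which drives it, at 0.92, and cathepsin L (CTSL1) at 0.88. Sarcomere genes fell in 18 of 46 and rose in 2 (the same adjusted over the list alone), such as troponin TNNI1 (-1.20). That list's adjusted p of 0.0346 became 0.891 with an estimated correlation, and it lost the call without scrambled ethanol replicate 1 (0.0898) or 2 (0.0924) or VDR siRNA ethanol replicate 2 (0.0564) or 4 (0.0638).

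**Figure D3:**
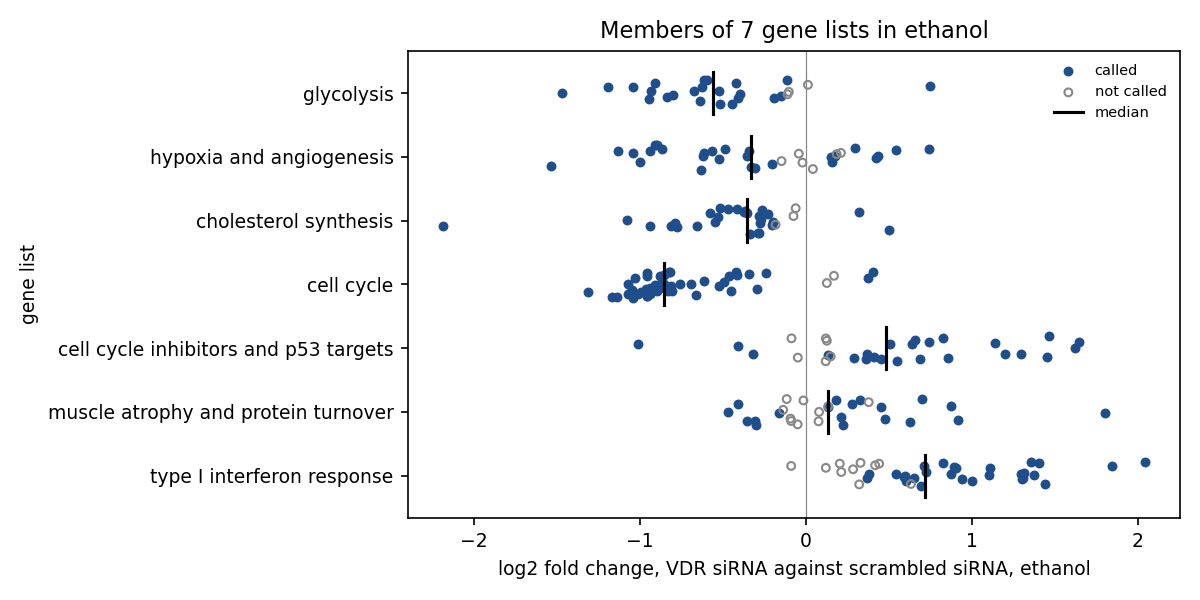
VDR siRNA effect in ethanol (log2 fold change) for each tested member of 7 gene lists, with filled points for called genes and a bar for the list's median. Cell cycle members lie mostly below 0 (43 of 47 called lower) and p53 targets mostly above (21 of 30 called higher).

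With calcitriol in the medium the VDR siRNA effect was largely shared. SCN4A rose by 4.06, PDK4 by 3.82 (3.94 to 55.6 CPM), CLCA2 by 3.44, PADI2 by 3.16, NTN1 by 3.07, the alcohol dehydrogenase gene ADH1B by 2.97, the neuronal pentraxin gene NPTX1 by 2.90, INPP5D by 2.86, MX1 by 2.74 and C1orf187 by 2.74. Among genes whose groups did not overlap, the named falls were CPA4 (-3.62, 87.9 to 7.16 CPM), ISM2 (-3.54), CYP24A1 (-3.43, SE 0.114, edgeR adjusted p = 2.17e-14), C2orf72 (-3.12), FAIM2 and APLN (both -2.82), MGAT3 (-2.54), L1CAM (-2.47) and SULT1C2 (-2.31). PTGIS, prostacyclin synthase, passed the rule (-2.57, adjusted p = 0.00196) through scrambled calcitriol replicate 1, without which it had -0.87 (adjusted p = 0.0676). There were 7895 called genes, 3948 higher and 3947 lower, with 558 and 485 of them changed at least 2-fold, and 26 of the 485 were among the unusual transcripts of scrambled calcitriol replicate 1. Of the 7527 genes called in ethanol, 7295 (96.9%) kept their sign with calcitriol, 6069 were called in the same direction, against 1601 met by chance, and 46 in the opposite one. Their median change was 0.387 and 0.361, and across these genes Pearson's r was 0.763 and Spearman's rho 0.921.

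The lists called with calcitriol were nearly those called in ethanol, with vitamin D receptor targets in place of the sarcomere. Of 51 receptor targets 22 were lower and 11 higher in VDR siRNA cells (25 and 11 adjusted over the list alone, adjusted p = 0.0107 with an estimated correlation), led by PFKFB4, a regulator of glycolysis (-1.18), and CYP24A1. Cell cycle (43 lower and 2 higher of 47), glycolysis (21 and 1 of 26), p53 targets (3 and 23 of 30), cholesterol synthesis (22 and 3 of 31) and hypoxia genes (19 and 6 of 33) held with an estimated correlation at adjusted p of 0.0167, 0.0107, 0.000561, 0.0214 and 0.0362. Adjusted over the list alone, glycolysis had 22 lower, and the other 4 kept these counts. Interferon genes (35 of 38 higher, adjusted p = 0.596 with an estimated correlation), the unfolded protein response (19 lower and 2 higher of 31, adjusted p = 0.209), matrix genes (28 lower and 12 higher of 52, adjusted p = 0.632) and muscle atrophy genes (15 higher and 7 lower of 29, adjusted p = 0.209) did not. Adjusted over the list alone, matrix genes had 29 lower and 14 higher, and the other 3 lists kept these counts.

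A pair of libraries held transcripts at levels well above those of their sister libraries. In scrambled calcitriol replicate 1, 49 genes stood at 1 CPM or more and at least 3-fold above each of the 14 other libraries. In VDR siRNA ethanol replicate 2 this held for 17 genes, against at most 5 in any other library. The receptor gene KIT stood at 58.5 and 10.3 CPM in these libraries, against 0.754 in the highest of the 14, and the chloride channel gene ANO1 at 20.7 and 6.14 CPM. Without both libraries the numbers of called genes were 1350, 5, 6928 and 7209 for the 4 pairwise comparisons in the order given, and 252 for the interaction.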

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

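Chosen after the result was seen were the tests of seed matches, of their grading and of GACGTA, the 3 tests of 1 shared source, the test of mast cells by level, the tests of a GC and length trend and of fewer molecules, the splits after removal of that trend, and the fits of KIT without its libraries. The tests of the share of lowered genes, of receptor loss, of the Cajal, mast and melanocyte marker counts, of the interferon list and of the 5 other sets of splits were written beforehand, though the pattern among VDR siRNA libraries was reworded after results were seen and its interferon test, first set aside, was run later with its original bound. That the interaction splits decide nothing was judged after their counts were seen.

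The calcitriol effect differed between the siRNAs for 331 genes by the interaction test, and 27 of them are named here (VDR siRNA minus scrambled siRNA, log2, edgeR adjusted p under 0.05). Genes that rose in scrambled siRNA cells and had a lower value with VDR siRNA were DPP4 (-2.26), TREM1 (-2.54), SHE (-2.86), PVALB (-3.15), SULT1C2 (-2.35), KCNS2 (-1.78), EFTUD1 (-1.43), HMCN1 (-1.32), OSR2 (-1.31), CLMN (-1.25), CHRDL1 (-1.24), NPTX2 (-0.88), TMEM119 (-0.88), ELFN2 (-0.70), SERPINE2 (-0.62), CYP3A7 (-0.59) and VEGFA (-0.29). A lower value can go with a higher ethanol level under VDR siRNA. In ethanol, VDR siRNA raised PVALB by 2.96, near the size of its interaction. HMCN1 stood there at 35.1 to 41 CPM, against 21.5 to 26.9 CPM in scrambled siRNA cells. CLMN did not differ in this way (12.5 to 13.3 against 11.6 to 13.5 CPM). Genes that fell in scrambled siRNA cells and had a higher value with VDR siRNA were SCG2 (1.56), FMO2 (1.26), EMILIN3 (1.19), SULT1E1 (1.13), CORIN (1.08), CIDEC (0.85), PDK4 (0.76), COL8A1 (0.64) and MSTN (0.60). A higher value can likewise go with a changed ethanol level, as VDR siRNA in ethanol raised PDK4 by 3.06 and MSTN by 1.14. The ethanol levels of the other genes that fell are not compared here. The value of KIT (-8.38) rests on 2 libraries, and was -2.63 (adjusted p = 0.298) without scrambled calcitriol replicate 1, -6.17 (0.111) without VDR siRNA ethanol replicate 2 and -0.41 (0.922) without both. Without both, VEGFA (-0.27) and MSTN (0.59) also missed the threshold (0.0809 each), and MSTN missed it without any 1 of scrambled ethanol replicates 2 (0.0666) and 4 (0.0681), scrambled calcitriol replicate 3 (0.0673), VDR siRNA ethanol replicates 1 (0.0775), 2 (0.0787) and 3 (0.0771), and VDR siRNA calcitriol replicates 2 (0.0569) and 3 (0.0623).

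A library far from its 3 sisters, with a gap to the nearest, as a share of the group's range, above Dixon's 95% critical value for 4 samples, was met in 20 of 284 groups of values, where chance gives about 14. KIT and PTGIS stood apart in scrambled calcitriol replicate 1 (0.997, 58.5 against 0.339 CPM, and 0.988, 17.2 against 1.79) and in VDR siRNA ethanol replicate 2 (0.986, 10.3 against 0.752, and 0.961, 3.53 against 0.927). CYP24A1 was highest in scrambled ethanol replicate 3 (1, the only library of that group with any fragment) and scrambled calcitriol replicate 3 (0.851, 318 against 262 CPM). In VDR siRNA ethanol replicate 4, CHRM2 (0.868, 0.601 against 0.283), MSTN (0.87, 5.91 against 5.08) and MFN1 (0.848, 43.7 against 38.6) were highest and PPARGC1A lowest (0.838, 2.39 against 2.9). In VDR siRNA calcitriol replicate 3, PPARGC1A (0.905, 3.77 against 2.69) and KCNS2 (0.86, 6.67 against 5.16) were highest and the number of detected genes lowest (0.849). In VDR siRNA calcitriol replicate 1, CORIN (0.884, 12.6 against 16.3) and FMO2 (0.878, 2.09 against 2.97) were lowest. The rest were ELFN2 in scrambled calcitriol replicate 3 (0.86, 156 against 136), PVALB in scrambled calcitriol replicate 4 (0.846, 2.42 against 1.84), RXRA in scrambled calcitriol replicate 2 (0.88, 84.4 against 80.5), and the interferon list mean in scrambled calcitriol replicate 4 (0.845, lowest) and VDR siRNA ethanol replicate 1 (0.853, lowest).

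With the libraries regrouped in every other way, only the real groups called as many genes for calcitriol in scrambled siRNA cells (1630, highest other split 1, 1 of 35 splits as large), for VDR siRNA in ethanol (7527, highest other 0, 1 of 35) and with calcitriol (7895, highest other 1, 1 of 35). These shares lie under the bound of 0.05 set beforehand and are the smallest that 35 splits allow. As the labels do not say what the replicates are, they bear only on how these libraries were grouped. For the interaction 2 of 100 drawn splits, the real one included, called as many genes (331, highest other 1000). Those 2 are the only drawn splits that keep the real groups of the scrambled siRNA libraries. Their counts hold the calcitriol effect in scrambled siRNA cells, while the other splits remove it. More splits that keep these groups exist but were not drawn, and the 2 drawn are too few for a share under 0.05. What a structure of the VDR siRNA libraries adds to the 1000 was not separated. For the number of genes called for calcitriol in VDR siRNA cells chance cannot be excluded, since 3 of 35 splits called at least the 10 genes of the real one and the others called 1841 and 885, which points to a structure of the samples. These splits bear on the count and not on CYP24A1, which had 0 fragments in the VDR siRNA ethanol libraries and 12584 with calcitriol.

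The number of genes that differed between VDR siRNA and scrambled siRNA cells has 2 kinds of candidate explanation, loss of the receptor and effects of the siRNA molecules themselves. Of 15895 words of 7 bases in the 3′ UTRs of 11470 genes, TCACCTC had the lowest t for VDR siRNA in ethanol (-15.01, lowest unrelated word -4.34) and with calcitriol (-13.05, -4.5), but not for calcitriol in scrambled siRNA cells (-1.16). In ethanol, genes matching TCACCTCA had an adjusted log2 difference of -0.3 (SE 0.021, 482 genes) from genes without a match. Their plain medians were -0.148 and 0.033. The t and the adjusted differences come from regressions that allow for 3′ UTR length and GC content and for mean expression. In them, log2 fold changes were limited to a size of 3. The lowering was graded over the 3 longer kinds of match, TCACCTCA, TCACCTC and CACCTCA (smallest step 0.064 over both media), as pairing of an siRNA seed would give. Genes with GACGTA had an adjusted difference of 0.22 in ethanol (SE 0.019, medians 0.128 with it and 0.001 without), as release from a seed of the scrambled siRNA would give. GACGTA did not stand alone as TCACCTC did. The word GACAGTA, which lacks it, had a t of 7.57 in ethanol, against 8.08 for GACGTAA. With calcitriol GACAGTA had 7.41, against 8.32 for AGACGTA. Of the named falls in ethanol, CPA4 and SCD held the 8-base match and VDR, MGAT3, APLN, ISM2 and CHRM2 a 7-base one. L1CAM and SEMA7A held only a 6-base match and C2orf72 none, while NTN1, which rose, held a 7-base one. In ethanol, cholesterol synthesis genes with a 7- or 8-base match had a median of -0.828 (4 genes), against -0.344 without. Matrix genes had -0.375 (14 genes) and -0.17, while glycolysis went the other way (-0.418 in 3 genes and -0.597). The 7-base and 8-base 3′ UTR matches could not account for most of the lowering, since 34.4% of the lowered genes had one against 20.8% of uncalled genes, and cell cycle genes without one had a median of -0.85. By the adjusted difference, genes with a 6-base match were lower too (-0.06, SE 0.012, medians 0.01 with it and 0.033 without any). So were genes with a match in the coding sequence (-0.11, SE 0.016, medians -0.054 and 0.043). How much these 2 kinds of match add stays open. Receptor loss stays open: over 6 splits of the control libraries the correlation of the calcitriol and VDR siRNA effects, which an opposite effect would make negative, had a median of 0.06 (-0.04 to 0.11), and without the siRNA sequences or a second siRNA the 2 kinds cannot be told apart for genes without a match.

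Transcripts such as KIT and ANO1, present in scrambled calcitriol replicate 1 and VDR siRNA ethanol replicate 2 and near 0 in their sisters, may come from RNA or reads of another source, and no biological explanation was tested. Whether 1 source served both libraries stays open after 3 tests, each devised once the one before was known: a rank correlation of the excess of 0.45 over 49 genes (permutation p = 0.0012) but 0.21 over the 17 genes of the other library (p = 0.43), 11 of 17 genes shared (95% interval 38.3 to 85.8%) and 5 of 17 higher in the first library (10.3 to 56%, the use of these intervals as bounds being chosen after the counts were seen). They point different ways, as do CD34 (0.359 and 16.1 CPM) and ALDH1A2 (27.8 and 0.0688 CPM), chosen after their values were seen. Markers counted as raised if, in either library, they exceeded the highest of the 14 others and reached 3 times their mean, a looser rule than the 3-fold one above. Of interstitial cell of Cajal markers not seen beforehand, 2 of 4 were raised, GPR20 and FOXF1, with ETV1 at 53 CPM in the 14 others, which decides nothing, and 6 of the 10 on that list were picked from these libraries. Mast cell markers other than KIT were raised in 3 of 7 cases, which leaves that source open by its own bound, but the highest reached 0.351 CPM in the library with 10.3 CPM of KIT and 0.23 CPM in the one with 58.5 CPM, which argues against it, as 0 of 7 melanocyte markers raised does against melanocytes.

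The VDR siRNA libraries differed from one another along an axis other than the treatment, since other splits of them called up to 1841 genes. With a trend in GC content and gene length removed from each library the highest other split called 2 genes and the real one 24 (1 of 35 splits). The correction was chosen after the uncorrected splits were seen, so this share does not exclude chance for the corrected count. A trend between libraries is a candidate source of this axis. Fewer distinct molecules in VDR siRNA calcitriol replicate 3 may add to it: at equal depth 17909 genes were detected against at least 18645 in the 15 others, but the excess of its scatter over that of its sisters was only 1.12 times greater at low than at high expression, so this cannot be told apart from other noise. For the interferon list alone, the biological explanation weighed, the outcome lay between the bounds set beforehand. The distance of that library to its sisters was 1.4 times their mutual distance without that list and 1.4 times with all genes. Removing the 38 listed genes did not lower it, so they did not account for it, while interferon genes outside the list were not tested.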

How the results depend on the processing

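Halved counts, both libraries with unusual transcripts left out, the lists without CYP24A1 and the GC and length correction were chosen after seeing the data. Where no cause is given, the cause was not tested. The gene counts of VDR siRNA stayed within 1.5 times under each alternative, and those of the other comparisons did so except as follows. For calcitriol in scrambled siRNA cells 2851 genes were called with only the compared libraries in the fit. For calcitriol in VDR siRNA cells it was 35 with DESeq2, 2 with only the compared libraries, 24 after the GC and length correction and 5 without both libraries with unusual transcripts, and for the interaction 504 with DESeq2 and 748 after that correction. Over the 16135 genes it covers, the correction moved the count for calcitriol in scrambled siRNA cells from 1516 to 2432. DESeq2 gave 30 genes called in both siRNAs. With an estimated correlation 3, 2, 5, 6 and 2 lists were called for the 2 calcitriol, the 2 VDR siRNA effects and the interaction, and without shared members 5 for calcitriol in VDR siRNA cells. Signs reversed for uncalled values of calcitriol in scrambled siRNA cells, MFN1 after the correction (-0.01) and PPARGC1A without both libraries (-0.15), for OPA1 under VDR siRNA in ethanol after the correction (0), and for the vitamin D metabolism list without CYP24A1 (0.989), which carried it. With 1 library left out, counts ran from 1231 to 1628, 3 to 15, 6834 to 7157, 7276 to 8070 and 255 to 415 in the order above, lists from 9 to 13, 3 to 11, 9 to 10, 10 to 10 and 8 to 10, and VDR from -2.04 to -1.94 in ethanol and -1.70 to -1.59 with calcitriol. Signs then reversed in MFN1 (-0.03 to 0.05) and PPARGC1A (-0.15 to 0.25) for calcitriol, in CYP24A1 for VDR siRNA in ethanol (-5 to 0, both groups being at the floor), and in the adjusted p of sarcomere and contractile genes, calcitriol effect in VDR siRNA cells (5.19e-05 without VDR siRNA calcitriol replicate 4 to 0.794 without replicate 3). Of 402 called results for named genes, 43 lost the call without some library, 30 without both libraries with unusual transcripts, 8 of 358 with only the compared libraries, 7 each with limma-voom and the replicate block, 4 with robust=TRUE, at most 2 under each other setting, none of 399 with DESeq2, and none of the 402 reversed. Of 14 uncalled ones, 3 became called after the GC and length correction, 3 of 13 with only the compared libraries, 3 times when a library was left out, and 1 each with DESeq2, limma-voom, RLE factors, the block, halved counts and both other filters. Replicate numbers did not pair the libraries (correlations -0.055 to 0.046 for equal and -0.057 to 0.114 for unequal numbers). The interaction could not be fitted with only the compared groups.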

Other observations

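Several metabolic genes moved under VDR siRNA in ethanol within lists that were not called as a whole. Citrate synthase (CS), the entry enzyme of the citric acid cycle, went from 152 to 68.9 CPM (-1.14), PDK1 fell by 0.86 and the mitochondrial isocitrate dehydrogenase IDH2 by 0.63, in a list with 13 of 31 genes lower and 8 higher (camera adjusted p = 0.302). Among 33 genes of fatty acid oxidation and lipid storage, 9 rose and 8 fell (adjusted p = 0.633), with the carnitine palmitoyltransferase CPT1A (1.32), the carnitine carrier SLC25A20 (1.12) and the lipid droplet protein PLIN2 (0.93) higher and PPARD (-1.12) lower. Of 77 nuclear OXPHOS genes 16 rose and 13 fell (adjusted p = 0.921, with COX8A at -1.23), and of 38 genes of mitochondrial dynamics and biogenesis 9 rose and 11 fell (adjusted p = 0.819), with GABPA, a regulator of nuclear genes for mitochondria, at 0.88. Calcitriol in scrambled siRNA cells left 0 of 77 OXPHOS genes called by edgeR (adjusted p = 0.176 for the list).

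Genes of differentiation and signalling went both ways in that comparison. Myogenic regulators had 12 of 35 lower and 9 higher (adjusted p = 0.609), with the receptor MET at 1.34 and SIX4 at -0.82, and calcium handling 12 of 40 lower and 8 higher (adjusted p = 0.704). The inflammatory list had 11 of 35 lower and 8 higher (adjusted p = 0.976), with the adhesion molecule VCAM1 at -1.61 and the innate receptor TLR2 at 1.39. The TGF-beta list had 10 of 29 higher and 8 lower (adjusted p = 0.985), and immediate early genes 11 and 11 of 27 (adjusted p = 0.921). Oxidative stress genes had 14 of 28 higher and 4 lower (adjusted p = 0.0749), with haem oxygenase HMOX1 at 1.01, and ribosomal proteins 13 of 68 higher and 5 lower (adjusted p = 0.326). Vitamin D receptor targets had 16 of 51 higher and 8 lower (adjusted p = 0.871), and vitamin D metabolism and receptor partners 4 of 25 higher and 6 lower (adjusted p = 0.674). Markers of other cells were mixed, with fibroblast 6 higher and 7 lower of 21 (adjusted p = 0.835), pericyte and smooth muscle 3 and 5 of 17 (0.175, PDGFRB at -1.14), endothelial 4 and 1 of 17 (0.375, KDR at 1.70), leukocyte 1 and 1 of 12 (0.921) and adipocyte 2 and 2 of 11 (0.819). The median, mean and test did not share a sign in the lists of OXPHOS, vitamin D metabolism, TGF-beta, inflammatory, immediate early, fibroblast and leukocyte genes.

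The mean log2 CPM of the 38 interferon genes was 3.31 ± 0.23 in scrambled ethanol, 2.99 ± 0.12 in scrambled calcitriol, 4.12 ± 0.16 in VDR siRNA ethanol and 4.07 ± 0.46 in VDR siRNA calcitriol libraries, where single libraries ran from 3.48 to 4.59. In ethanol the 100 most abundant genes took 34.4% of the counts in VDR siRNA libraries and a larger share in each scrambled siRNA library (exact permutation p = 0.0286, n = 4 per group, adjusted p = 0.172 over 24 comparisons). The first 2 principal components held 23.1 and 12.2% of the variance, and the second set 1 library apart, VDR siRNA calcitriol replicate 3 at -98.7 against -11.3 to 23.5 in the other 15.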
